A study of Acipenser sturio with 24 samples.

How the data were processed

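RNA of whole sturgeon embryos was sequenced at 24 developmental stages, with 1 library per stage. Per the labels, the animals were Bester hybrids, a cross of beluga and sterlet sturgeon, while the organism field of the same labels names another sturgeon species, Acipenser sturio. Stages are given on the Nieuwkoop-Faber (NF) scale, a staging table drawn up for the frog Xenopus. Total RNA was depleted of ribosomal RNA before library construction, per the labels' protocols, so transcripts without a poly(A) tail can be represented. The submitters' processing notes name CASAVA 1.8.2, Trimmomatic, Bowtie and RSEM, without a role or an order. The series title also names Xenopus laevis, which was not analysed here.

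The deposited table holds a signal per assembled component and library, an abundance that was normalized before deposit. The component identifiers have the form that a de novo transcriptome assembly gives, and the assembler is not given in the sources used here. The table has 275906 components and 24 library columns, all of which were mapped to a stage through the labels (0 columns unmapped). The values are not read counts: they have 2 decimals, only 0.458% of those above 0 are whole numbers, and the column totals run from 342953 to 679612. The steps of the low values differ between components, as they do after division by transcript length. Whether the unit is FPKM or TPM, and whether libraries were scaled to each other, is not given in the sources used here. The files do not pair components with gene names, so the gene lists drawn up before the data were examined were not tested and no gene is named.

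Absolute sequencing depth is unknown. The value that 1 read is worth was compared between libraries from the modal ratios of low values, over 243 of 276 library pairs, of which 100% lay within 0.1 (log2) of the fitted values. Reads per unit of value, relative to stage 36, ran from 0.629 at stage 29 to 3.41 at stage 4, a ratio of 5.42. Whole reads per component were not recovered, since component lengths were not used here. Thinning libraries to an equal depth was therefore not run, and detection was counted as a value of at least 1.

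The plan made before the data were examined assumed counts. A count-based quasi-likelihood test with trimmed-mean scaling had been planned, and it was replaced by limma 3.58.1 (R 4.3.3) on log2(scaled value + 1), with a mean-variance trend and robust empirical Bayes variances. A fold change on this scale understates the change of low components. The trimmed mean of log ratios, unweighted on such values, gave factors from 0.455 at stage 12.5 to 1.53 at stage 36. Libraries were instead scaled by the median of ratios over the 14428 components above 0 in every library, with factors from 0.618 at stage 15 to 1.41 at stage 36. That choice was made before any calls were examined, and what drives the difference between the factors was not tested. Components with a value of at least 1 in at least 4 libraries were kept, which left 48818. The Benjamini-Hochberg adjusted p threshold was 0.05.

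The change over development was tested with a natural cubic spline of stage order with 4 degrees of freedom. Windows were fixed before the data were examined: cleavage-blastula (stages 0 to 9, 4 libraries), gastrula (stages 10 to 12.5, 5 libraries), neurula (stages 13 to 20, 7 libraries) and tailbud (stages 22 to 36, 8 libraries). Window means were compared in a model over all 24 libraries. There were no replicates of a stage. The p-values measure the scatter of neighbouring stages round a curve or within a window, which includes development inside the window, and nothing in the labels says how many embryos or clutches a library holds. Correlations with stage order were tested with two-sided permutation tests of 100000 shuffles, or by exact enumeration of the 5040 orders of 7 libraries. The components named are the 2 with the highest and the 2 with the lowest log2 change in the comparison with the most calls, past the threshold and with no overlap between the windows, a rule fixed before the data were examined.

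The models were tested on simulated data with 48818 components, of which 100 changed by 1 and 100 by 2 on the log2 scale. The simulated noise was independent between components and had the spread of the residuals about the stage curve. It held no development within a window, and changes were placed only in components with a mean log2 value above 1. The recovered shares can therefore exceed what the real window tests recover. At a log2 change of 2 the recovered share was 78% for the stage curve, 91% for gastrula against cleavage-blastula, 94% for neurula against gastrula and 97% for tailbud against neurula. At a log2 change of 1 these shares were 13%, 45%, 43% and 64%. Between 3 and 8 of 48618 unchanged components were called.

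The residuals about the stage curve divided the libraries into 2 sets that the labels do not record. The first principal component of the residuals of 2258 abundant components (mean of at least 20) held 34.2% of their variance, and the libraries were divided at the widest gap of its scores. Set B held stages 0, 13, 16, 19, 24, 29 and 36, and set A the other 17 libraries. Because the sets were read from the expression values, they are not groups of the study, and they were used to recompute results within a set or with the set as a model term. Other alternatives were column totals, the trimmed mean or no further scaling, other filters and pseudocounts, other spline settings and window edges, a minimum fold, summing rows that share a component number, and leaving out each library in turn. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used for the remaining steps.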

Results

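The data comprised whole-embryo transcriptomes of Bester hybrid sturgeon at NF stages 0 to 36, with 1 library for each of 24 stages. Values are abundances per assembled component that were normalized before deposit, without gene names. Summed values per library ran from 342953 at stage 12.5 to 679612 at stage 36, and reads per unit of value differed up to 5.42-fold between libraries.

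Libraries of neighbouring stages resembled each other, which addresses whether the series runs in stage order. The mean Spearman correlation across components was 0.804 between neighbouring stages and 0.565 over all pairs. No shuffled order reached the neighbour value, at the smallest p that 100000 permutations can give (1e-05). The most similar library was a direct neighbour for 14 of 24 libraries, for 14 of 17 within set A and for 7 of 7 within set B. The mean neighbour correlation was 0.839 within set A (permutation p = 1e-05) and 0.710 within set B (exact p = 0.000397). Components are not independent replicates, and these correlations describe the libraries.

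Stages 8 to 11 formed a block of nearly equal libraries, with pairwise correlations from 0.904 to 0.912. The correlation of stage 11 with stage 12 was 0.876, that of stage 12 with stage 12.5 was 0.795, and stage 0 correlated with stage 22 at 0.338 and with stage 36 at 0.472. The lowest correlation of any pair was 0.33, between stages 13.5 and 29.

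**Figure D1:**
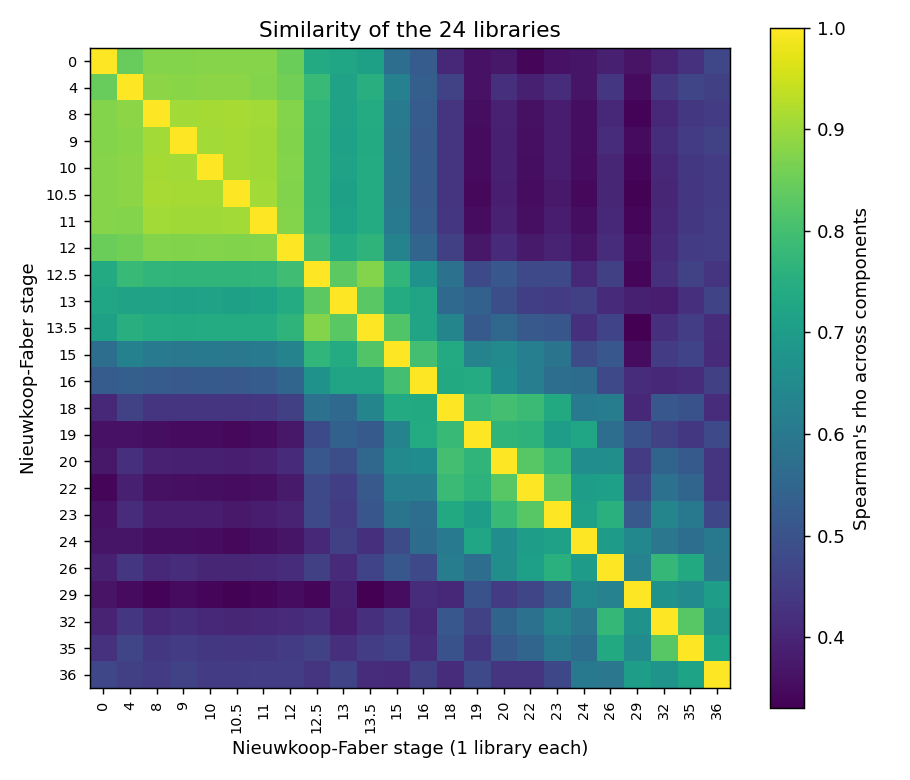
Spearman correlation across 48818 components between the 24 libraries, ordered by NF stage on both axes, with colour giving rho. Stages 8 to 11 form a block between 0.904 and 0.912, and the lowest value is 0.33, between stages 13.5 and 29.

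The number of detected components rose with stage, to an extent that depends on the value taken as detection. The number of components at a value of 1 or more averaged 15686 ± 519 (SD, 4 libraries) in the cleavage-blastula window, 15706 ± 938 (SD, 5 libraries) in the gastrula window, 24343 ± 8457 (SD, 7 libraries) in the neurula window and 45387 ± 8491 (SD, 8 libraries) in the tailbud window. These SDs include development within a window. The number was 14416 at stage 12.5, 35688 at stage 19 and 60863 at stage 29, the library with the fewest reads per unit of value. It rose with stage order (Pearson r = 0.901, permutation p = 1e-05, adjusted p = 2.25e-05; Spearman rho = 0.923, permutation p = 1e-05, adjusted p = 4.5e-05), and r was 0.893 without the 2 libraries farthest from the median stage. Within set A r was 0.926 (permutation p = 1e-05, the smallest possible) and rho 0.843 (permutation p = 4e-05). Within set B r was 0.886 (exact p = 0.00556) and rho 0.964 (exact p = 0.00278). At a value of 5 or more the window means were 7005, 6565, 6829 and 9794 in the same order, so the neurula mean did not exceed the cleavage-blastula mean. The correlation with stage order was then lower (r = 0.768, permutation p = 3e-05, adjusted p = 5.4e-05; rho = 0.679, permutation p = 0.00044, adjusted p = 0.00099), and r was 0.758 without the 2 farthest libraries. It was 0.771 within set A (permutation p = 0.00046) and 0.753 within set B (exact p = 0.0486). The adjustment covered 9 relations.

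The abundance held by a few components fell over the same stages. The 10 most abundant components of each library held 50.5% of the summed value at stage 0, 58.4% at stage 12.5, 36.8% at stage 19 and 22.8% at stage 36. Their share fell with stage order (r = -0.888, raw permutation p = 1e-05, adjusted p = 2.25e-05; rho = -0.815, permutation p = 1e-05, adjusted p = 4.5e-05), and r was -0.891 without the 2 libraries farthest from the median stage. Within set A r was -0.889 (permutation p = 1e-05) and within set B -0.871 (exact p = 0.00893).

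**Figure D2:**
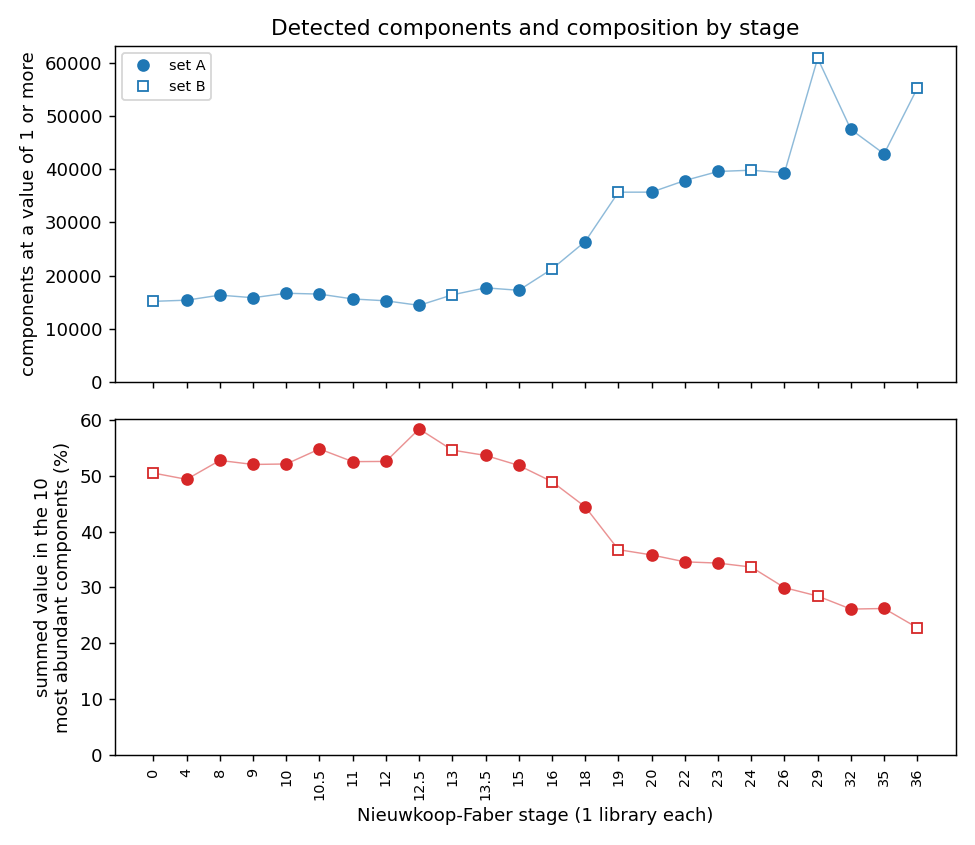
Number of components at a value of 1 or more (upper panel) and share of the summed value in the 10 most abundant components (lower panel, percent) by NF stage, 1 point per library, with filled circles for set A and open squares for set B. The number goes from 15168 at stage 0 to 55234 at stage 36 while the share goes from 50.5% to 22.8%.

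Most components changed over the series. The stage curve called 44175 of 48818 components (limma, adjusted p threshold 0.05). Of these, 27791 (62.9%) had their highest window mean in the tailbud window, 8929 (20.2%) in the neurula window, 3136 (7.10%) in the gastrula window and 4319 (9.78%) in the cleavage-blastula window. A fitted range of at least 4-fold was reached by 12194 of them, 7519 with the tailbud mean highest and 1270 with the cleavage-blastula mean highest. The tailbud majority is to be read against a general shift. The median log2 difference of tailbud from early libraries across all components was 0.91, and 0.75 to 0.98 under the 4 scalings. The filter also bears on it. A value of 1 or more was reached by 45387 components on average in the tailbud window and 15686 in the cleavage-blastula window. How much of the majority the shift and the filter account for was not tested. Within set B alone 5220 components were called, with 7 libraries and a spline of 2 degrees of freedom.

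No component was called between the gastrula and the cleavage-blastula window, a comparison that asks what changed after the early cleavages. limma called 0 of 48818 components, and 427 had an unadjusted p under 0.05. That share is below the 0.05 that unchanged components give on average. The spread in this test includes development within the windows, so 0 calls do not show that nothing changed. The window libraries of stages 10, 10.5 and 11 resembled those of stages 8 and 9. With stages 10 to 11 counted as cleavage-blastula, an edge chosen after the data were examined, 322 components were higher and 3 lower at stages 12 and 12.5. A log2 change of 1 was recovered in 45% of simulated components. The simulation held no development within a window, so the real test can recover less and changes could go undetected.

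Neurula libraries differed from gastrula libraries in a large share of the transcriptome. Of 48818 components, 20783 (42.6%) passed limma's adjusted p threshold, with 16937 that rose and 3846 that fell. Those that rose had a median log2 change of 1.01 (median SE 0.274) and those that fell -0.95 (median SE 0.272), and 1631 rose and 97 fell at least 4-fold. The median over all tested components was 0.41, and rises are to be read against this shift, which lay between 0.30 and 0.41 under the 4 scalings. The share of calls that rose was 81.5%, and 67.6% after scaling to column totals. Within set A alone 21477 components were called, 17590 of which rose, and set B has no gastrula library. With a minimum fold of 2, 965 components passed (941 up, 24 down). With stages 10 to 11 counted as cleavage-blastula the count was 5193.

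The 2 components with the highest change in this comparison rose from low values in the gastrula window. comp263949_c2 had a mean deposited value of 8.42 ± 8.77 (SD, 5 libraries) in the gastrula window and 2573 ± 2757 (SD, 7 libraries) in the neurula window, a log2 change of 7.42 (SE 0.875, limma adjusted p = 3.25e-06). It stood at 139 at stage 13.5, reached 7271 at stage 20 and stood at 3094 at stage 36. comp268053_c0 went from 3.12 ± 2.07 (SD, 5 libraries) to 517 ± 486 (SD, 7 libraries), a log2 change of 6.37 (SE 0.730, adjusted p = 2.56e-06).

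The 2 components with the lowest change fell from moderate early values. comp259142_c0 fell from 75.3 ± 31.3 (SD, 5 libraries) to 8.28 ± 12.0 (SD, 7 libraries), a log2 change of -3.64 (SE 0.659, adjusted p = 0.000188). comp201575_c0 fell from 22.5 ± 11.7 (SD, 5 libraries) to 2.43 ± 2.50 (SD, 7 libraries), a log2 change of -2.69 (SE 0.490, adjusted p = 0.000166). The latter then rose to 19.0 ± 14.6 (SD, 8 libraries) in the tailbud window, a log2 change of 2.07 (SE 0.433, adjusted p = 0.000565). Both stood lower in some set B libraries than at the set A stages on either side. comp201575_c0 was 34.8 at stage 26, 9.97 at stage 29 and 36.7 at stage 32. Within set A the neurula changes were -3.37 (adjusted p = 0.00174) and -2.35 (adjusted p = 0.00172). Non-overlapping windows were held by 5154 called components. Libraries in random order would give them for 0.253% of components. The stages are ordered and these components had already been called, so that rate is no measure of chance for them.

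**Figure D3:**
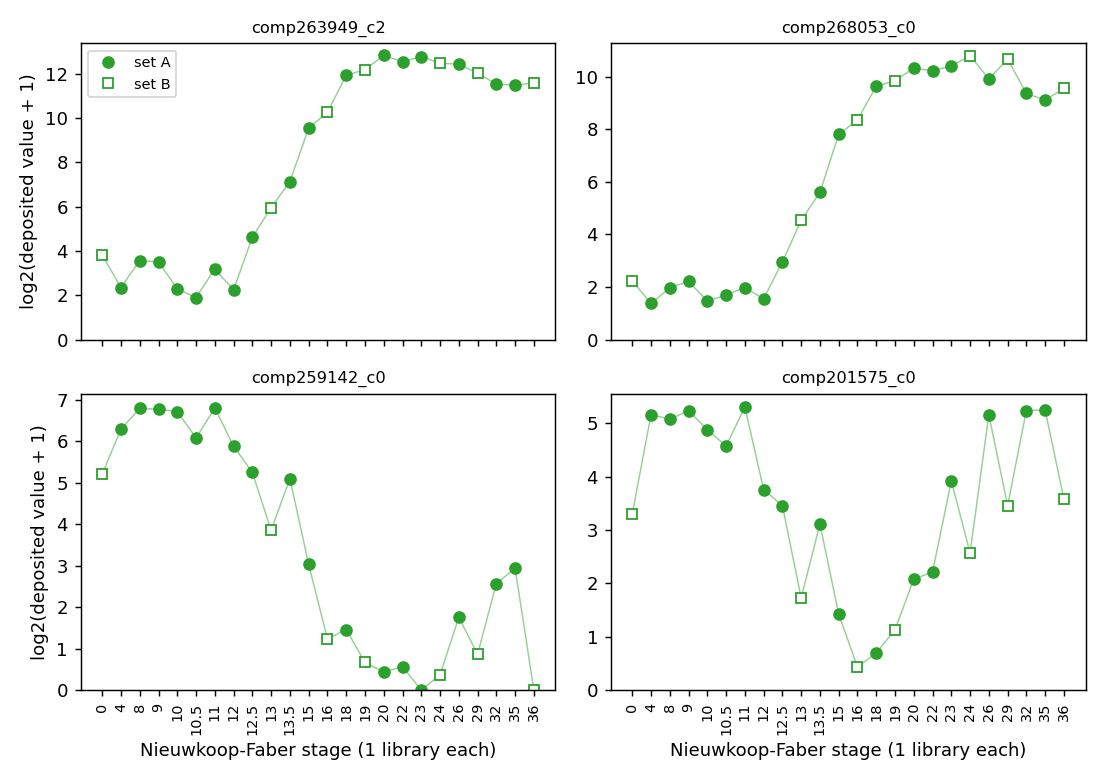
Deposited value of the 4 named components, as log2(value + 1), by NF stage, 1 point per library, with filled circles for set A and open squares for set B. comp263949_c2 goes from 3.73 at stage 12 to 7271 at stage 20, and comp201575_c0 is lowest at stage 16 (0.35).

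Tailbud libraries differed from neurula libraries in a similar number of components. Of 48818, 18777 (38.5%) passed the threshold, 14487 rising and 4290 falling. The median log2 change was 0.84 among those that rose (median SE 0.216) and -0.89 among those that fell (median SE 0.247), and 820 rose and 199 fell at least 4-fold. The median over all components was 0.26, and 0.12 to 0.47 under the 4 scalings. The share that rose was 77.2%, against 64.8% with the trimmed mean and 91.4% with values as deposited. Rises were in less excess among components with a value of at least 5 in at least 4 libraries, where 3258 rose and 2547 fell. Within set A 14160 components were called (11646 up, 2514 down) and within set B 826 (656 up, 170 down). Of the 14160, 13548 (95.7%) had the same direction in set B, against 81.0% of all tested components, and the 789 called in both sets all had the same direction. With a minimum fold of 2, 582 components passed (487 up, 95 down).

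Steps between neighbouring set A stages were smallest from stage 8 to stage 11, where between 8 and 36 components differed at least 4-fold. From stage 4 to 8 the number was 119, of which 116 were lower at stage 8. Between stages 12 and 12.5 it was 769, of which 732 were higher at stage 12.5, and between stages 15 and 18 it was 820. Later steps were not all large, with 74 components from stage 12.5 to 13.5, 68 from stage 20 to 22 and 67 from stage 22 to 23. Among all libraries, 383 components differed between stages 0 and 4, which belong to different sets. Each step compares 1 library with 1 library and has no replicate check.

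**Figure D4:**
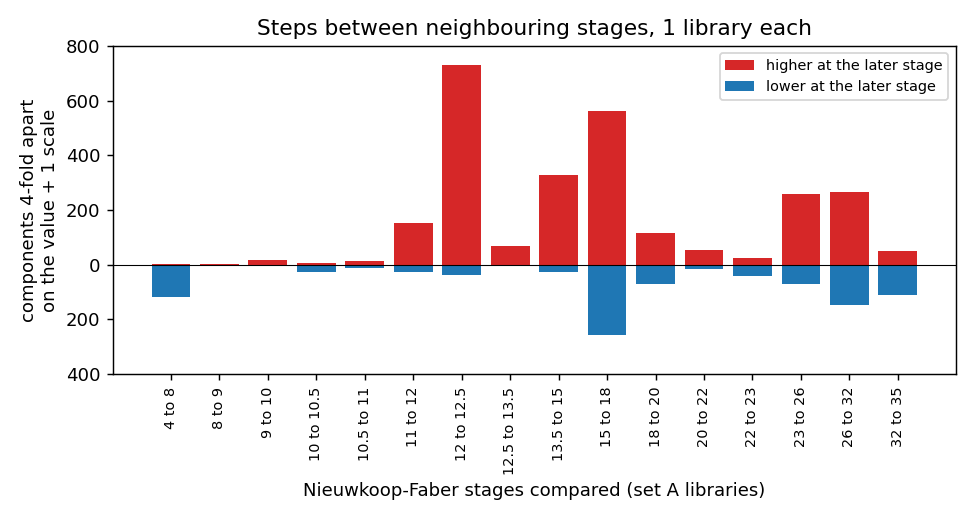
Number of components at least 4-fold higher (above 0) or lower (below 0) at the later of 2 neighbouring set A stages, on the value + 1 scale, 1 library each. The step from stage 12 to 12.5 has 732 higher and 37 lower, and that from stage 8 to 9 has 3 higher and 5 lower.

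A scaled value of 1 or more in every library of stages 0 to 11 was held by 10514 components. Of these, 6066 (57.7%) had a tailbud mean within 2-fold of their early mean, 497 stood at least 4-fold higher and 731 at least 4-fold lower. The folds were taken on the value + 1 scale, on which components low at early stages can hardly fall 4-fold, so these numbers depend in part on it. Those 731 alone held 6.45% of the summed value at stage 0 and 0.511% at stage 36. The 5093 components under 0.5 through stages 0 to 11 and at 5 or more later held 0.0449% at stage 0 and 5.28% at stage 36. Both classes were defined after the data were examined, in a way that itself places most of their change after stage 11. Their sizes were 1340 and 3740 after scaling to column totals, where the components at least 4-fold higher numbered 374.

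**Figure D5:**
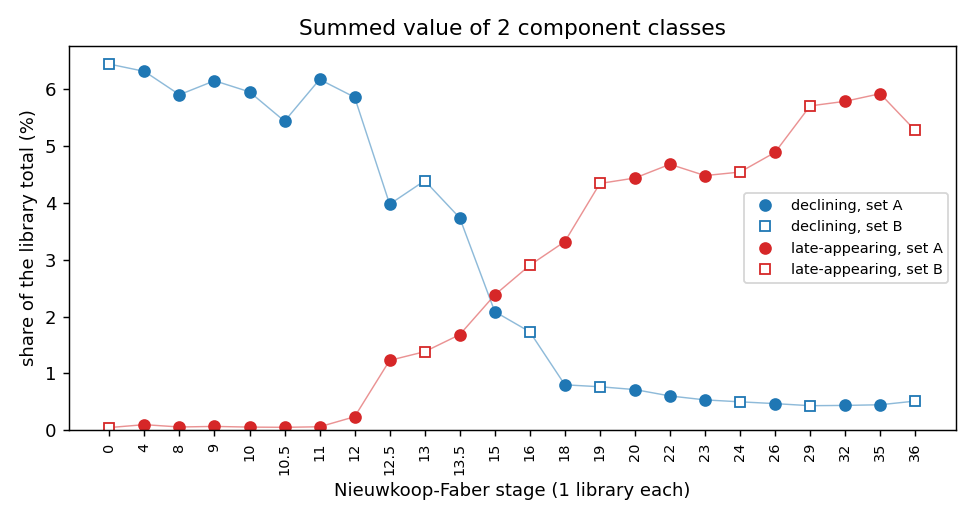
Share of each library's summed value (percent) in the 731 declining and the 5093 late-appearing components by NF stage, 1 point per library, with filled circles for set A and open squares for set B. The declining class holds 3.74% at stage 13.5 and 2.09% at stage 15, and the late-appearing class 1.68% and 2.38%.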

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

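No library stood far enough from the others of its window to be listed in any of 24 combinations of window and library measure, where chance alone lists about 1 in 20. Stage 29 held 60863 components at a value of 1 or more, the highest number in the series.

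The comparisons were set against other divisions of the same libraries, 100 in each case with the real one included, tests described after their results were seen. Random divisions break up the stage order, so they bear on chance only and do not show that a change lies at a window edge. For the stage curve 1 of 100 orders, the real one, gave as many calls (44175, highest other 21529). For neurula against gastrula 1 of 100 gave as many (20783, highest other 16498), and for tailbud against neurula again 1 of 100 (18777, highest other 14681). Each is the smallest share that 100 divisions can give. Since libraries resemble their neighbours, a division along stage order was likely to give the most calls. The counts make an unordered series unlikely and show no more. The highest other divisions follow stage order in part. For tailbud against neurula it joined stage 24 to the neurula libraries and so nearly repeats the real one, and for neurula against gastrula it set stages 10, 10.5, 11, 12.5, 13, 13.5 and 15 against 12, 16, 18, 19 and 20. Counting stage 22 as neurula gave 24565 calls against gastrula, more than the window edge fixed beforehand. For gastrula against cleavage-blastula all 100 divisions gave at least the real count of 0, with 1 as the highest other.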

How the results depend on the processing

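Scalings other than the planned column totals, pseudocounts, library sets and the edge at stages 10 to 11 were chosen after seeing the data. The stage curve called 113717 of 275906 components without a filter, 11727 of 12778 at a value of at least 5, and 5220 in set B alone, where both the libraries and the spline (2 degrees of freedom) differed. The other 11 alternatives stayed within 1.5 times. Gastrula against cleavage-blastula stayed at 0 in 14 alternatives, and reached 325 with stages 10 to 11 counted as cleavage-blastula and 248 with only stages 0 to 12.5 as well. Neurula against gastrula gave 6800 at a value of at least 5, 965 with a minimum fold of 2, and 5193 with stages 10 to 11 moved. Tailbud against neurula gave 33860 without a filter, 5805 at a value of at least 5, 582 with a minimum fold of 2, and 826 in set B alone. The filters change how many components are tested. With the edge moved, the gastrula window held only stages 12 and 12.5, and why the counts changed was not tested. Leaving out each library in turn gave 43615 to 44364, 0 to 0, 16635 to 24465 and 16256 to 21109 calls for these results.

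The neighbour correlation (0.800 to 0.817 with a library left out), the rise of detected components (0.887 to 0.919) and the fall of the top share (-0.905 to -0.872) kept direction and threshold in every alternative run. So did the 4 named components, in 4 alternatives each. Count-based tests, thinning and gene-list tests were not run, since the values are not counts and carry no gene names. Depth as reads is unknown, which limits statements on components near a value of 1. No paired analysis was possible because each stage has 1 library.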

Other observations

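The component classes and most tests in this part were chosen after seeing the data. The tests of a scaling factor and of sibling components, and those of steps among abundant components, within set A and between stages 4 and 12.5, had their bounds written before their results were seen. The tests of depth in set B, of reads per unit at later stages and of the 10 most abundant components, the abundant steps within set A and the direction between stages 4 and 12.5 did not.

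A component was called early-present when its scaled value was at least 1 in every library of stages 0 to 11, which held for 10514 components. Of these, 731 stood at least 4-fold lower in the tailbud mean than in the mean of stages 0 to 11. Another 497 stood at least 4-fold higher. The stage test was passed by all 731 and by 496 of the 497. It used the same libraries as this choice and passed 44175 of all 48818 components, so these passes are no separate evidence. A further 6066 early-present components (57.7%) lay within 2-fold. All these folds are on the value + 1 scale, on which components low at early stages can hardly fall 4-fold. The 731 declining components held 6.45% of the summed value at stage 0, 5.86% at stage 12, 3.98% at stage 12.5, 2.09% at stage 15 and 0.797% at stage 18. Their choice requires presence through stage 11 and a low tailbud mean, so it largely fixes that the fall lies between these. Their number depends on scaling, and was 1340 with column totals and 1257 with the trimmed mean. Within set A it was 732. The components at least 4-fold higher numbered 374 with column totals, 330 with the trimmed mean and 549 within set A.

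Late-appearing components stayed under 0.5 in every library of stages 0 to 11 and reached 5 or more later, which places their appearance after stage 11 by choice. There were 5093, and 3740 with column totals. Of the 5093, 5066 passed the stage test, which used the same libraries as this choice and is no separate evidence. At stage 12, 196 of them were at 1 or more, at stage 12.5 1229, at stage 15 2574 and at stage 20 3841. Their share of the summed value was 0.235% at stage 12, 1.23% at stage 12.5 and 5.92% at stage 35, and it passed that of the declining class at stage 15 (2.38% against 2.09%). Among 3774 such components reaching 5 in set A libraries, the stage at which the most reached 50% of their maximum was stage 18, with 911, followed by stage 15 with 595. Stage 16 is in set B, so stage 18 directly follows stage 15 here. The intervals between set A stages are unequal, and the ranking depends on them. The class of transient components, which can overlap the late-appearing one, held 991. Their highest value within stages 12 to 16 was 5 or more and at least 4 times every value of stages 0 to 11 and 32 to 36. Stages between 16 and 32 were not part of this rule, so a component of the class can stand higher there. Of the 991, 973 passed the stage test, again in the libraries used for the choice.

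Neighbouring stages from 8 to 11 differed less than those from stage 11 to 12.5. Between 8 and 36 components moved 4-fold in each step from stage 8 to 11, 180 (154 up) from 11 to 12, and 769 (732 up) from 12 to 12.5. Steps were larger before stage 8 (383 from stage 0 to 4, 119 from 4 to 8), and some later ones were small (67 from stage 22 to 23). Each step compares single libraries and has no replicate check. The libraries of stages 8 to 12.5 are all in set A, so the difference between their steps does not run along the library sets. Within set A the largest step from stage 11 on was 6.9 times the largest before it. That later step, from stage 15 to 18 with 820 components, lies outside stages 8 to 12.5, so the ratio does not test this difference. Counting noise and depth of single libraries stay open. Among abundant components the ratio of the largest step from stage 11 on to the largest before it was 2.0 over all libraries. Both of its steps, from stage 0 to 4 and from stage 26 to 29, cross sets. Within set A the ratio was 5.12 (counting spread 1.14), too near the bound of 5. Its later step was again stage 15 to 18, with 123 abundant components, against 83 from stage 12 to 12.5. Between stages 4 and 12.5, the 2 libraries with the most reads per unit of value, 86 abundant components differed 4-fold against 24 between stages 4 and 8, a ratio of 3.58 (counting spread 0.827) that lies too near its bound of 3. Of the 86, 85 (98.8%, exact 95% interval 93.7% to 99.97%) were higher at stage 12.5, which goes against noise without a direction. On values as deposited it was 58 of 69 (84.1%, 73.3% to 91.8%), so the share depends on the scaling and passed its bound only on scaled values. The intervals treat components as independent, which they are not.

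The 7 libraries of set B stood apart from the other 17. Sequencing depth does not account for all of them, since the worth of 1 read lay inside the range of the other libraries in 4 of 7. A single scaling factor per library does not either, since all 7 still scored above the other 17 after each library was centred, which removes such a factor. For parental forms assembled as sibling components, 46.2% of 437 sibling pairs (SE 2.38) went in opposite directions, against 49.5% for independent directions. The bound set for this explanation was 54.3%, which is 2 standard errors above the latter, so no excess of opposite pairs was seen. Siblings that move together would lower the share and could hide such pairs, so the test cannot decide the question. Clutch, embryo pool and library batch also stay open, the labels give none of them, and no other biological explanation was tested.

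More components reached a value of 1 at later stages. Fewer reads per unit of value do not account for the whole rise. In the 2 tailbud libraries where 1 read is worth no more than in the median library of stages 0 to 12.5, the lower number of components was 2.27 times the highest early number. A smaller share of the 10 most abundant components does not account for the whole rise either. After leaving those out and rescaling each library to an equal remaining total, the ratio of tailbud to cleavage-blastula means was 1.68, against 2.89 before. The rescaling also removes differences in column totals, which averaged 418968 in the cleavage-blastula and 577781 in the tailbud window. The drop in the ratio cannot be credited to either alone. At a value of 5 or more the ratio on values as deposited was 1.40.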
